A study of Mus musculus with 8 samples.

How the data were processed

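RNA was sequenced from cultured mouse cortical neurons, with 8 libraries in 4 groups of 2 biological replicates: Control, Control with KCl, Rem2 KO and Rem2 KO with KCl. Per the labels, neurons from embryonic day 16.5 cortex were grown for 6 days, silenced with 1 µM tetrodotoxin overnight, and in the KCl groups depolarised with 55 mM KCl for 4 h. Libraries were made with an Illumina TruSeq kit from 500 ng of total RNA. The genotype field reads Rem2 flx/flx for all 8 libraries, the removed exons and the source of Cre are not stated, and the groups were taken from the library titles. Per the submitters' processing notes, reads were aligned with TopHat and quantified with Cufflinks on mm10 (versions not stated). The values are FPKM computed by the authors, deposited as 1 value per RefSeq transcript and library, per the file headers.

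The file held 34915 transcript entries (29974 NM and 4941 NR accessions), and 94 of them had no value in the libraries numbered 2. Of 34353 accessions 34015 were matched to a gene, and the 338 others held 0.313% to 0.502% of the FPKM sum of a library. FPKM values of the transcripts of a gene were summed. The 302 genes with a repeated accession or a missing value, among them Jund, Rims1 and Aqp4, were left out, which left 23830 genes. Read counts were not used here because the values are FPKM, and whole reads were not recovered from the FPKM values, so the planned tests on counts were not run. The smallest steps between low FPKM values gave a rough depth of 18.2 to 20.4 M fragments in the libraries numbered 1 and 34.5 to 40.0 M in those numbered 2. FPKM sums per library were 435544 to 474624, and the 10 most abundant genes held 5.01% to 6.81%. Exact zeros in genes that are abundant in other libraries were treated as values, since a failed estimate by the software and an absent transcript look alike in the file, and such genes are given per library.

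Genes with FPKM of at least 1 in at least 2 libraries (13089) were tested on log2(FPKM + 1) without rescaling, with limma 3.58.1 (empirical Bayes with a variance trend) in R 4.3.3. The model had a mean for each of the 4 groups (4 residual degrees of freedom). The 6 contrasts were the KCl effect in each genotype, the genotype effect in each KCl state, the averaged genotype effect, and the interaction. P values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. These choices, the comparisons, the gene-naming rule and the variations of processing were fixed before the data were examined. Whether replicate numbers pair the libraries was checked by correlating the deviations of same-numbered libraries from their group means, which gave 0.708 to 0.783 over the 6 pairs of groups. The replicate number was therefore also fitted as a block (3 residual degrees of freedom), a variation set beforehand.

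The analysis used 27 gene lists fixed in advance by function or cell type, of which 26 had tested members. The mitochondrially encoded list had none. The other lists were immediate-early genes, late activity-regulated effectors, RGK GTPases, synaptogenic molecules, glutamate receptors, postsynaptic density, presynaptic release, GABAergic synapse, calcium channels, calcium-calmodulin signalling, sodium and potassium channels, axon guidance, interferon, p53, integrated stress response, cholesterol synthesis, glycolysis and hypoxia, and ribosomal proteins. Marker lists covered excitatory neurons, interneurons, astrocytes and radial glia, proliferation and progenitors, oligodendrocyte lineage, microglia, endothelial and mural cells, and meningeal fibroblasts. Lists were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, all in limma. Members were also adjusted over the list alone.

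Named genes were Rem2, Gem, Rem1 and Rrad, then per contrast up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold with non-overlapping groups and a mean of at least 2 FPKM in a group. Predicted, microRNA and small nucleolar genes were skipped. Where fewer than 10 passed, the 10 smallest p values were named as values that did not pass. From each list up to 4 members past the threshold, or the 2 with the smallest p, were named. Other genes in the text were chosen after their values were seen.

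Variations set beforehand were pseudocounts of 0.1 and 0.5, no filter, a minimum of 5 FPKM, upper quartile, TMM-type and quantile scaling, the replicate block, no variance trend, array weights, a fit of only the 4 libraries compared, leaving out each library, and a fold of at least 1.5. Variations added after the data were seen were genes above 0 in all 8 libraries, the block combined with that restriction, with quantile normalization or with pseudocount 0.1, keeping the genes left out, testing transcripts, each set alone, and the block without each library. The calls were tested on simulated data with 200 changed genes of 13089 in 5 runs. With the block 4.55% of calls were false for the averaged genotype effect, and 97.8% of log2 changes of 1 were recovered for the effect without KCl, against 0% without the block. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.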

Results

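Transcript abundance was measured by RNA sequencing in cultured mouse cortical neurons labelled Control or Rem2 KO. Rem2 encodes a small GTPase of the RGK family, whose members are known to inhibit voltage-gated calcium channels. The neurons came from embryonic day 16.5 cortex and were grown for 6 days, with 1 µM tetrodotoxin, a blocker of voltage-gated sodium channels, added overnight from day 5. On day 6 part of the cultures was depolarised with 55 mM KCl for 4 h, and the others stayed silenced. The 8 libraries form 4 groups (Control, Control with KCl, Rem2 KO, Rem2 KO with KCl) of 2 biological replicates each, numbered 1 and 2. The deposited values are FPKM without read counts, so total counts per library are unknown. Steps in the lowest values place the depth roughly at 18.2 to 20.4 M fragments in the libraries numbered 1 and at 34.5 to 40.0 M in those numbered 2. Between 11949 and 12717 genes reached 1 FPKM in a library, and 13089 genes were tested.

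Replicate number was the largest source of variation among the libraries. Principal component 1 (49.0% of variance) separated the 4 libraries numbered 1 (set 1) from the 4 numbered 2 (set 2), component 2 (32.5%) separated KCl from no KCl, and component 3 held 4.57%. Log2 values of libraries that shared number and KCl state but not genotype correlated across genes at 0.979 to 0.982. Replicates of 1 group correlated at 0.912 to 0.929, which is lower. Each count of changed genes is therefore given without a replicate term, as planned, and beside it with the replicate number as a block where this moved the count by more than 1.5 times. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM, and adjusted p values are from limma.

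**Figure D1:**
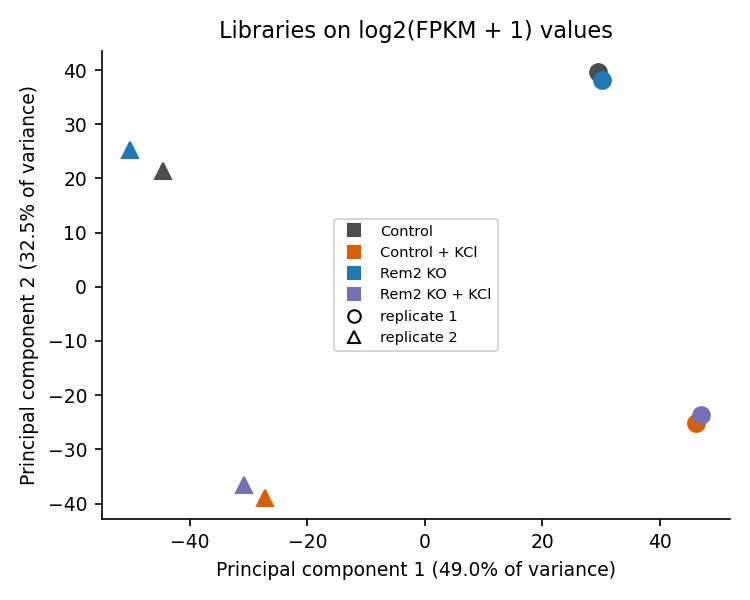
Principal components 1 and 2 of the log2(FPKM + 1) values of the 8 libraries, with colour for the group and shape for the replicate number. Component 1 (49.0% of variance) parts the replicate numbers and component 2 (32.5%) parts KCl from no KCl, while Control and Rem2 KO libraries with the same number and KCl state lie close together.

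Rem2 itself (chromosome 14, 54476100 to 54480434, mm10) was measured first as a check of the labels. Its level was 6.29 and 2.54 FPKM in Control replicates 1 and 2, and 2.13 and 1.70 FPKM in Rem2 KO. With KCl it was 22.5 and 21.4 FPKM in Control and 11.7 and 12.4 FPKM in Rem2 KO, so Rem2 was lower in Rem2 KO in all 4 pairs of same-numbered libraries. The genotype difference averaged over both KCl states was a log2 fold change of -0.81 (SE 0.23), and it did not pass the test over all genes (adjusted p = 1 without the block and 0.167 with it). KCl raised Rem2 by 2.18 (SE 0.33, adjusted p = 0.0110) in Control and by 2.16 (SE 0.33, adjusted p = 0.0123) in Rem2 KO. The values cover the whole gene, and which exons were to be removed is not stated, so the level left in Rem2 KO does not show how much functional transcript remained. Gem, another RGK member, went from a mean of 2.27 to 5.29 FPKM with KCl in Rem2 KO (log2 fold change 0.96, adjusted p = 0.0264). In Control its mean went from 2.42 to 4.75 FPKM (0.75), short of the threshold without the block (adjusted p = 0.0502) and past it with the block (adjusted p = 0.00856). Rrad reached at most 1.52 FPKM and passed in both genotypes only with the block (adjusted p = 0.0205 in Control and 0.0155 in Rem2 KO), and Rem1 was too low to be tested.

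**Figure D2:**
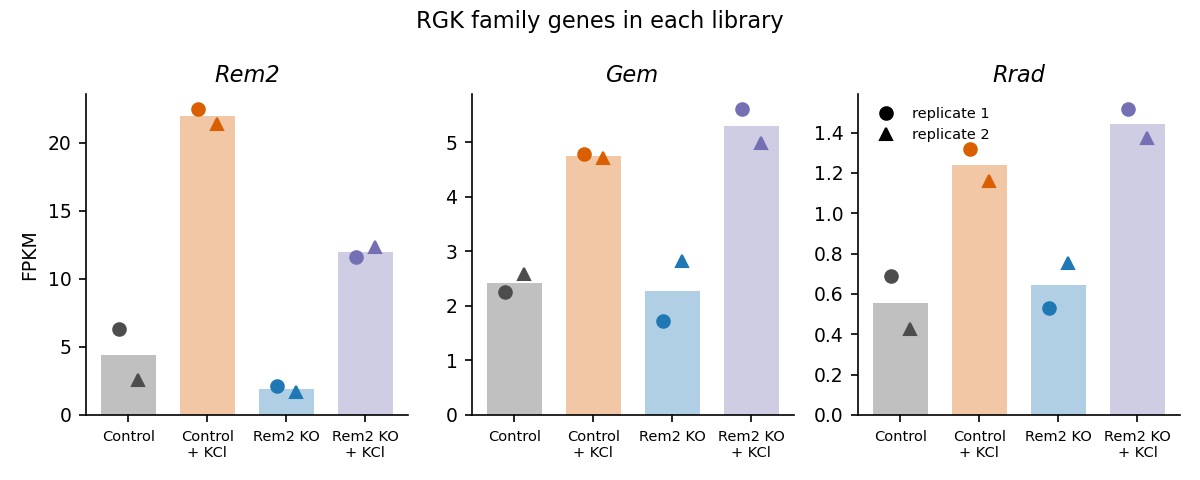
FPKM of Rem2, Gem and Rrad in each library, with points for the replicates and bars for the mean of the 2 libraries of a group. Rem2 is higher with KCl in both genotypes and lower in Rem2 KO than in Control in every pair of same-numbered libraries.

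Among genes detected in every library, depolarisation of Control neurons raised Pcsk1, Fosb, Npas4, Bdnf and Fos most on the log2(FPKM + 1) scale. Bdnf, a neurotrophin (chromosome 2, 109674700 to 109727043), rose from 0.411 ± 0.00917 to 25.7 ± 1.70 FPKM (SD, n = 2). This was an 18.9-fold change of FPKM + 1 (limma adjusted p = 0.000326). Pcsk1, a prohormone convertase, rose 28.5-fold in FPKM + 1, from 1.12 ± 0.0970 to 59.9 ± 10.2 FPKM (limma adjusted p = 0.000616, n = 2). Fos (chromosome 12, 85473890 to 85477274) rose 18.1-fold in FPKM + 1, to a mean of 161 FPKM. The other large rises were Fosb (log2 fold change 4.74), Npas4 (4.40), Nr4a3 (3.88), Vgf (3.87) and Nr4a1 (3.64). Among falls of genes detected in every library, the largest were Ntsr1, a neurotensin receptor (22.6 to 2.62 FPKM, log2 fold change -2.73), Sla, which encodes an Src-like adaptor (55.4 to 13.1 FPKM, -2.01), and AI854703 (-1.95). Ttc19 was listed at 0 in both Control libraries and at 25.0 and 28.7 FPKM with KCl, and Cmc1 at 21.2 and 18.1 FPKM without KCl and at 0 in both libraries with it. Txndc11 was likewise listed at 0 without KCl, and Ric3, Fam13c, Agbl5, Tmco6, B3gntl1 and Ccdc73 were listed at 0 with KCl.

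Immediate-early genes rose as a group in Control neurons: 15 of 26 measured members rose, by 1.06 to 4.74 on the log2 scale, none fell, and 11 did not pass (16 rose adjusted over the list alone). The list passed camera with the preset correlation (adjusted p = 1.04e-15) but not with an estimated one (adjusted p = 0.106 with an estimated correlation). Of 30 late activity-regulated effectors, 23 rose and none fell (26 adjusted over the list alone), among them Scg2 (22.8 to 259.9 FPKM) and the neuropeptide gene Sst (183 ± 52.6 to 1134 ± 191 FPKM, n = 2). This was the list whose call held with an estimated correlation (adjusted p = 4.68e-27 preset and 0.00594 estimated, 0.0714 estimated with the block). Among RGK genes, Rem2 alone of 3 passed without the block, and all 3 passed with it and adjusted over the list alone (camera adjusted p = 0.00702, and 0.261 with an estimated correlation).

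Synaptic lists held rises and falls in Control neurons, and some of both depended on scaling. Of 76 synaptogenic adhesion and secreted molecules 9 rose and 5 fell (9 and 7 adjusted over the list alone; 14 and 5 under quantile normalization), with rises of Bdnf, the pentraxin Nptx2 (3.06) and Lrrc4 (1.56), a postsynaptic adhesion molecule, and a fall of the synapse organiser Cbln1 (21.3 to 7.30 FPKM, -1.44). Its median change was -0.05 while its mean was 0.13 and its camera test upward (adjusted p = 0.0386, and 0.634 with an estimated correlation), and the median turned to 0.09 under quantile normalization. In the postsynaptic density list 5 of 25 rose, led by Homer1 (18.0 to 82.2 FPKM), and 1 fell (5 and 2 adjusted over the list alone; 7 and 3 under quantile normalization; adjusted p = 0.0386, and 0.726 with an estimated correlation). Glutamate receptors had 3 rises (Grm2, Cacng3 and Grin1) and 6 falls, including Grm5 (-0.67), of 32, the same counts adjusted over the list alone, against 4 rises and 2 falls under quantile normalization (adjusted p = 0.604). In presynaptic genes 3 of 36 rose, among them Sv2c (2.32) and Snap25 (0.78), and 2 fell (3 and 1 adjusted over the list alone; 6 and 0 under quantile normalization; adjusted p = 0.146). The GABAergic synapse list had 6 rises of 20, led by the GABA-synthesising enzymes Gad1 (50.9 to 195 FPKM) and Gad2 (14.3 to 43.1 FPKM), and 1 fall (7 and 0 under quantile normalization). Adjusted over the list alone 9 rose and 2 fell (adjusted p = 0.00343, and 0.261 with an estimated correlation).

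Ion channel and calcium signalling genes included both rises and falls. Of 15 voltage-gated calcium channel subunits none rose and Cacna1d (8.02 to 3.16 FPKM), Cacna1i (-0.999) and Cacna1b (-0.46) fell (5 falls adjusted over the list alone, and 2 under quantile normalization). The camera adjusted p was 0.301 and the fry adjusted p 0.00840 downward. Fry tests against no change, and the list median of -0.16 was near the -0.14 of all genes. Under quantile normalization the list median was -0.0022. Sodium and potassium channels had 8 rises of 41, among them Kcna1 (2.08), Kcnj4 (1.84) and Kcnj3 (1.72), and 11 falls, among them Kcng1 (-1.45), against 11 rises and 4 falls under quantile normalization. Adjusted over the list alone there were 9 rises and 15 falls, and the camera test gave adjusted p = 0.794. Calcium-calmodulin genes had 7 rises of 33, led by the transcriptional regulator Crem (6.23 to 47.4 FPKM), and 5 falls, led by the calcineurin subunit Ppp3cc (-1.30), the same counts adjusted over the list alone (adjusted p = 0.0437, and 0.353 with an estimated correlation).

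The remaining lists held few changed genes in Control neurons without the block. Axon guidance genes had 3 rises (Epha3, Nrp1 and Efna5) and 4 falls of 39 (the same counts adjusted over the list alone; 5 and 0 under quantile normalization, where the list median turned from -0.13 to 0.08; adjusted p = 0.556). Interneuron markers rose for Gad1, Gad2 and Sst of 17 (6 adjusted over the list alone; adjusted p = 6.1e-05, and 0.261 with an estimated correlation). Excitatory neuron markers rose for Fezf2 (1.94) and Neurod6 (0.88) of 17 (1 adjusted over the list alone; adjusted p = 0.0088, and 0.353 with an estimated correlation). In the p53 list Sesn2 (1.17) and Zmat3 (0.47) rose and Bbc3 (-1.10) fell of 20 (2 and 0 adjusted over the list alone; 3 and 0 under quantile normalization; adjusted p = 0.0283, and 0.726 with an estimated correlation). Sesn2 was also the 1 gene of 21 that rose in the integrated stress response list (1 adjusted over the list alone; adjusted p = 0.0088, and 0.591 with an estimated correlation). Glycolysis and hypoxia genes had 3 rises, led by the neuronal glucose transporter Slc2a3 (23.5 to 86.2 FPKM), and 2 falls of 20, the same counts adjusted over the list alone (adjusted p = 0.0126, and 0.394 with an estimated correlation). Cholesterol synthesis genes had 1 rise (Cyp51, 0.90) and 2 falls (Dhcr7, -1.23, and Nsdhl, -0.53) of 20 (0 and 1 adjusted over the list alone; 1 and 1 under quantile normalization; adjusted p = 0.0783). Neurog2 (0.85) rose among 18 proliferation and progenitor markers, Mog (-0.95) fell among 10 oligodendrocyte lineage markers and Stat2 (-1.04) fell among 13 interferon-stimulated genes (0, 2 falls and 1 fall adjusted over the list alone; adjusted p = 0.0783, 0.611 and 0.728). No marker of astrocytes and radial glia (17 measured), microglia (13), endothelial and mural cells (9) or meningeal fibroblasts (8) and no ribosomal protein gene (26) passed without the block, over all genes or adjusted over the list alone (adjusted p from 0.221 to 0.580).

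Across all genes KCl raised 678 and lowered 1600 of 13089 genes in Control neurons (2278 in total; 6367, of which 1881 rose, with the block). The share of rises was 29.8% as deposited, 48.6% after TMM-type scaling, which moved the median gene by 0.17 on the log2 scale, and 44.0% after quantile normalization, which moved it by 0.15. Without Control replicate 1 or 2 the fit called 242 or 466 genes (240 and 460 of them among the 2278), and without Control with KCl replicate 1 or 2 it called 126 or 136 (119 and 135 among them). The share of rises was 59.9%, 48.7%, 64.3% and 69.1% in these fits, so the excess of falls shrank to 239 against 227 rises without Control replicate 2 and turned to an excess of rises in the other 3.

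The response of Rem2 KO neurons to KCl involved the same leading genes. Pcsk1 rose 27.8-fold in FPKM + 1, from 1.07 ± 0.402 to 56.1 ± 5.95 FPKM (limma adjusted p = 0.000551, n = 2). Bdnf rose 16.7-fold in FPKM + 1, from a mean of 0.563 to 25.2 FPKM. Fos rose from 7.52 ± 1.90 to 177 ± 2.82 FPKM (limma adjusted p = 0.000392, n = 2). Fosb (4.80), Npas4 (4.75), Nr4a3 (4.05), Nr4a1 (3.98), Vgf (3.76) and Scg2 (3.59) also rose. Ntsr1 (-2.53), Sla (-2.00), AI854703 (-1.99), Cbln1 (-1.50) and Grm3 (-1.45) fell. Ttc19, Cmc1, Fam13c, Tmco6 and B3gntl1 were listed at 0 in 1 KCl state, as in Control. Igfbp7, which encodes a secreted growth factor-binding protein, was listed at 0 in Rem2 KO alone, Surf1 in Rem2 KO with KCl alone, Dnlz everywhere but in Rem2 KO, and Slx4ip in Rem2 KO with KCl and in replicate 1 of Control with KCl.

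Of the lists in Rem2 KO neurons, 16 of 26 immediate-early genes rose and none fell (20 adjusted over the list alone; adjusted p = 3.15e-16, and 0.1002 with an estimated correlation). Among late effectors 22 of 30 rose and none fell (28 adjusted over the list alone; adjusted p = 2.74e-26, 0.00629 with an estimated correlation, and 0.0749 with that and the block), including Nptx2 (3.26) and Cdkn1a (1.57). Rem2 and Gem rose among 3 RGK genes (3 adjusted over the list alone; adjusted p = 0.0055, and 0.370 with an estimated correlation). The synaptogenic list had 11 rises and 5 falls of 76 (15 and 9 adjusted over the list alone; adjusted p = 0.167). The postsynaptic density list had 5 rises, with Homer1 at 2.03 and Baiap2 at 1.54, and 1 fall of 25 (5 and 2; adjusted p = 0.0215, and 0.710 with an estimated correlation). Glutamate receptors had 1 rise and 7 falls of 32 (2 and 8 adjusted over the list alone; 3 and 5 under quantile normalization; adjusted p = 0.353). Presynaptic genes had 4 rises and 2 falls of 36, unchanged over the list alone (4 and 0 under quantile normalization; adjusted p = 0.216). GABAergic genes had 6 rises and 2 falls of 20 (8 and 3 over the list alone; 6 and 1 under quantile normalization; adjusted p = 0.0728), with a median of -0.07, a mean of 0.20 and a median of 0.14 under quantile normalization. Among calcium channel subunits Cacna1g (8.09 to 13.6 FPKM, 0.68) rose and 4 of 15 fell, among them Cacna1d (-1.14), Cacna1i (-0.98) and Cacna2d2 (-0.83), the same counts adjusted over the list alone and 2 rises and 2 falls under quantile normalization (adjusted p = 0.630).

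Sodium and potassium channels in Rem2 KO neurons had 9 rises, led by Kcnj4 (2.28), and 9 falls of 41 (13 and 12 adjusted over the list alone; 11 and 4 under quantile normalization; adjusted p = 0.745). Calcium-calmodulin genes had 5 rises, with Crem at 2.71, and 4 falls of 33, with Ppp3cc at -1.42 (7 and 5 over the list alone; adjusted p = 0.0737, and 0.0435 with the block). Axon guidance genes had 3 rises and 4 falls of 39 (unchanged over the list alone; 5 and 1 under quantile normalization; adjusted p = 0.704). Interneuron markers rose for the same 3 genes, with Sst at 2.44 (3 over the list alone; adjusted p = 0.00168, and 0.370 with an estimated correlation). Excitatory markers rose for Fezf2 and Rorb (3 over the list alone, and 0 under quantile normalization; adjusted p = 0.00709, and 0.383 with an estimated correlation). The p53 list had 4 rises and no fall (5 and 1 over the list alone; adjusted p = 0.00895, and 0.710 with an estimated correlation). The integrated stress response list again had Sesn2 alone (1 over the list alone; adjusted p = 0.00554, and 0.575 with an estimated correlation). Cholesterol synthesis had 1 rise and 1 fall, as over the list alone (adjusted p = 0.00371, and 0.710 with an estimated correlation). Glycolysis and hypoxia genes had 5 rises and no fall (5 and 1 over the list alone; 3 and 1 under quantile normalization; adjusted p = 0.00214, and 0.370 with an estimated correlation). Neurog2 rose, though not under quantile normalization, and Mog fell, as in Control (0 and 0 over the list alone; adjusted p = 0.132 and 0.981), and the interferon, astrocyte, microglia, endothelial, fibroblast and ribosomal lists had no changed member by either adjustment without the block (adjusted p from 0.430 to 0.916). In total KCl raised 750 and lowered 1349 genes in Rem2 KO (2099; 6216, of which 2103 rose, with the block), a share of rises of 35.7%, against 47.4% after TMM-type scaling, which moved the median gene by 0.12, and 44.7% after quantile normalization. Without Rem2 KO replicate 1 or 2 the count was 931 or 422, without Rem2 KO with KCl replicate 1 or 2 it was 200 or 715, and without Control with KCl replicate 1 or 2 it was 1241 or 1254. The share of rises turned to 62.3% without Rem2 KO replicate 2, to 63.0% without Rem2 KO with KCl replicate 1 and to 77.8% with only the 4 libraries compared (45 genes), and was 37.6% to 39.8% in the other fits that left out a library.

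With the block, which respects the pairing of the libraries, more list members passed for KCl. In Control and Rem2 KO in turn, 20 and 22 immediate-early genes rose and 1 and 2 fell, and 28 and 29 late effectors rose and 1 and 0 fell. Synaptogenic genes had 20 and 19 rises and 18 and 20 falls, glutamate receptors 5 and 4 rises and 13 and 13 falls, and postsynaptic density genes 9 and 9 rises and 5 and 6 falls. Presynaptic genes had 9 and 10 rises and 10 and 10 falls, and GABAergic genes 9 and 8 rises and 2 and 4 falls. Calcium channel subunits had 1 and 3 rises and 7 and 5 falls, sodium and potassium channels 13 and 14 rises and 19 and 18 falls, and calcium-calmodulin genes 10 and 10 rises and 8 and 7 falls. Axon guidance genes had 6 and 7 rises and 13 and 18 falls, beside 1881 and 2103 rises and 4486 and 4113 falls over all genes. Excitatory markers had 8 and 9 rises and no fall, and interneuron markers 8 and 7 rises and 1 and 1 falls. The p53 list had 7 and 8 rises and 1 and 1 falls, integrated stress response 6 and 6 rises and 2 and 1 falls, cholesterol synthesis 4 and 8 rises and 4 and 1 falls, and glycolysis and hypoxia 7 and 11 rises and 4 and 1 falls. Proliferation markers had 4 and 4 rises and 2 and 2 falls, astrocyte markers 1 and 1 rises and 1 and 2 falls, oligodendrocyte markers 3 and 3 falls and interferon genes 3 and 2 falls. No microglia or endothelial marker passed in either genotype. As rises, 1 fibroblast marker and 1 ribosomal protein gene passed in Rem2 KO and not in Control, which is no test of a difference.

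Whether the knockout changes the size of the KCl response was asked by setting both responses side by side. Over the 4373 genes changed by KCl on average, the response in Rem2 KO was set against that in Control. The slope, with equal error on both axes, was 1.00 and r was 0.943 across genes, which are not independent replicates. Within set 1 the slope was 0.996 (r = 0.916) and within set 2 it was 1.00 (r = 0.934). Of these genes 99.8% had the same sign, which choosing them by the average of both effects favours. Genes chosen by the KCl effect in Control alone gave a slope of 0.953, r = 0.943 and 99.6% of the same sign. Those chosen by the effect in Rem2 KO alone gave 1.05, r = 0.945 and 99.6%. Of the rises 589 were shared, against 38.9 for independent lists, and of the falls 1222, against 165. Both lists share each gene's variance estimate, so these numbers are a reference and no test. The interaction test found 1 gene, Igfbp7, and 68 genes at an unadjusted p under 0.05 by limma (9 genes with the block, each listed at 0 in some library, and 452 unadjusted). Without Control replicate 1 or without Rem2 KO replicate 2 the call of Igfbp7 ended, and limma called 0 genes. Igfbp7 read 19.998 and 19.2 FPKM in Control, 21.3 and 17.8 in Control with KCl, 0 and 0 in Rem2 KO, and 17.0 and 17.8 in Rem2 KO with KCl (interaction adjusted p = 0.00475). Among genes detected in every library, the smallest interaction p values belonged to Bcat2, which encodes a mitochondrial aminotransferase of branched-chain amino acids (9.94 to 2.87 FPKM in Control and 6.21 to 6.46 in Rem2 KO). Next came Grm2, a metabotropic glutamate receptor (4.19 to 12.6 FPKM in Control and 4.37 to 6.57 in Rem2 KO, interaction -0.89). Neither passed (adjusted p = 1), nor did Rspo3 (-0.71), Surf2 (0.80), Nefl (0.47) or Cacna1g (0.45). Surf2 overlaps Surf1 on chromosome 2 (26916372 to 26920187 against 26913378 to 26916610). It read 39.8 and 40.2 FPKM in Rem2 KO with KCl, where Surf1 was listed at 0, and 20.9 to 29.7 FPKM elsewhere. The cause was not tested. No list member passed the interaction test. By camera with the preset correlation the KCl effect was more positive in Rem2 KO for immediate-early genes (median 0.17, adjusted p = 0.0109) and cholesterol synthesis (0.24, 0.000419). It was more negative for axon guidance (-0.03, 0.000997), GABAergic (-0.08, 0.00899), glutamate receptor (-0.03, 0.0229) and interneuron (-0.11, 0.0274) lists. For interneuron markers the median KCl effect was lower in Rem2 KO in set 2 alone (0.28 against 0.41, and 0.38 against 0.33 in set 1). For glutamate receptors the medians did not follow the test (-0.20 against -0.21 in set 1 and -0.24 against -0.27 in set 2). With an estimated correlation the adjusted p was 0.705 for cholesterol synthesis and 0.535 for each of the others. With the block glycolysis and hypoxia genes passed (adjusted p = 0.0282, and 0.824 with an estimated correlation) and glutamate receptors did not (0.0963).

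**Figure D3:**
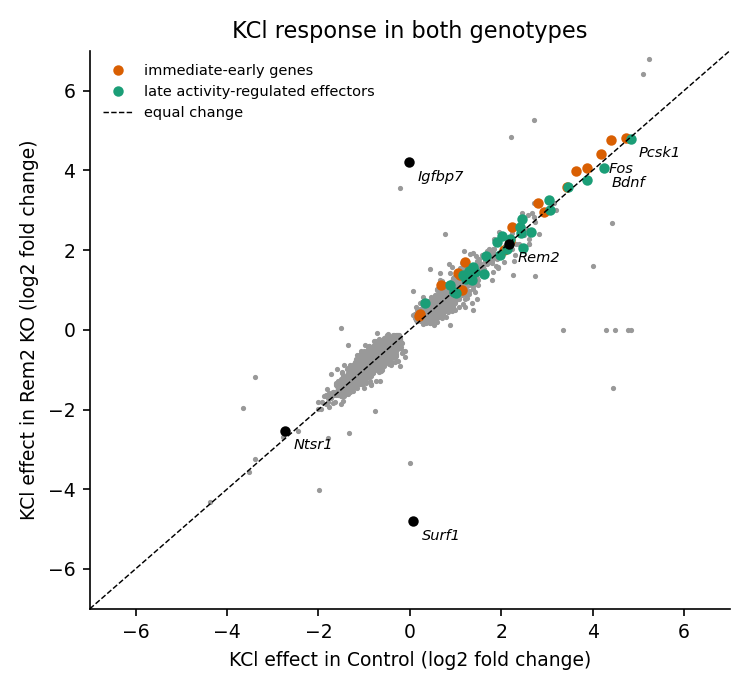
KCl effect in Rem2 KO (vertical, log2 fold change) against the KCl effect in Control (horizontal) for the 4373 genes changed by KCl on average, with Rem2, Ntsr1, Igfbp7 and Surf1 in black. Immediate-early genes and late effectors lie along the line of equal change, and Igfbp7 and Surf1, listed at 0 in 1 Rem2 KO group, lie far from it.

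In silenced neurons few genes separated Rem2 KO from Control. The 3 genes that passed, Igfbp7 (lower in Rem2 KO, adjusted p = 0.000494), Dnlz (higher, adjusted p = 0.00766) and Mir1249 (higher, adjusted p = 0.00985), were each listed at 0 in both libraries of a group. Dnlz was listed at 9.77 and 8.65 FPKM in Rem2 KO and at 0 in the other 6 libraries. The microRNA gene Mir1249 was listed at 0 in both Control libraries, at 49.8 and 46.6 FPKM in Rem2 KO, at 22.5 and 19.1 in Control with KCl, and at 24.2 and 11.5 in Rem2 KO with KCl. With the block 4 genes passed, and the added gene, Gpc5, was detected in every library (log2 fold change -1.18, adjusted p = 0.0159 with the block and 1 without). Of genes detected in every library, the smallest p values without the block belonged to Rasl12 (1.05), Slc26a7 (0.94) and Nwd2 (-0.73), and the calcium channel gene Cacna1g was at -0.43 (8.09 FPKM in Rem2 KO against 11.3), all with adjusted p = 1. At an unadjusted p under 0.05 limma counted 181 genes, and 1003 with the block. Without a library of Control or of Rem2 KO, 1 of the 3 genes still passed.

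No member of a fixed list passed in silenced neurons without the block, over all genes or adjusted over the list alone. Lower in Rem2 KO by camera with the preset correlation were sodium and potassium channels (median log2 fold change -0.13, 5 of 41 members above 0, adjusted p = 3.88e-06, and 0.0886 with an estimated correlation) and calcium channel subunits (-0.10, 3 of 15 above 0, adjusted p = 0.000387, and 0.158 with an estimated correlation). So were cholesterol synthesis genes (-0.24, 0 of 20 above 0, adjusted p = 3.95e-05, and 0.694 with an estimated correlation) and excitatory neuron markers (-0.17, adjusted p = 0.0267, and 0.542 with an estimated correlation). Under quantile normalization the excitatory markers did not pass camera with the preset correlation (adjusted p = 0.109), and the synaptogenic list did (0.0392). Higher were markers of astrocytes and radial glia (0.11, 16 of 17 above 0, adjusted p = 0.000389), oligodendrocyte lineage (0.23, adjusted p = 0.000387), proliferation and progenitors (0.20, adjusted p = 0.00518) and interneurons (0.11, adjusted p = 0.00377), with adjusted p = 0.542, 0.285, 0.731 and 0.542 with an estimated correlation. The block added the synaptogenic (adjusted p = 0.0182), presynaptic (0.0166), microglia (0.00608) and endothelial (0.0166) lists as lower and the p53 list (0.00488) as higher, with adjusted p = 0.397, 0.397, 0.397, 0.595 and 0.397 with an estimated correlation.

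In depolarised neurons 6 genes separated Rem2 KO from Control, all listed at 0 in some library. Surf1, which encodes a cytochrome c oxidase assembly factor, was listed at 0 in both libraries of Rem2 KO with KCl and at 33.9 and 21.3 FPKM in Control with KCl (30.2 and 21.5 in Control, 20.5 and 35.2 in Rem2 KO; adjusted p = 0.0370). Agbl5 was listed at 0 in both libraries of Control with KCl and at 3.14 and 3.10 FPKM in Rem2 KO with KCl (8.47 and 10.6 in Control, 8.02 and 8.86 in Rem2 KO; adjusted p = 0.0370). The microRNA genes Mir1898, Mir674, Mir93 and Mir7063 had values in Control with KCl alone (limma adjusted p = 0.0370 to 0.0372). In replicates 1 and 2 of that group they read 41.9 and 18.2, 39.2 and 17.7, 31.4 and 14.4, and 27.5 and 12.7 FPKM in turn. None of the 6 passed when a library was left out, except that 4 did without replicate 2 of Control with KCl. In the other 7 fits limma called 0 to 2 genes, none of them among the 6, and 115 to 184 at an unadjusted p under 0.05. With the block 10 genes passed, 3 of them detected in every library: Gpc5 (-0.999, adjusted p = 0.0224), Slf1 (-0.77, adjusted p = 0.0312) and the cortical transcription factor Bhlhe22 (52.4 to 30.7 FPKM, -0.76, adjusted p = 0.0312). Genes with the smallest p values that did not pass by either fit were Gpr85 (178 to 104 FPKM, -0.76, adjusted p = 0.757), Gucy1b1 (-0.51, adjusted p = 0.757) and Zbtb18 (-0.76, adjusted p = 0.757), followed by Lmo1 (-0.83), Grm2 (-0.84), Ccdc85a (-0.80), Sema7a (-0.49) and C2cd4b (1.20). The unadjusted count by limma was 195 genes, and 984 with the block.

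Axon guidance genes were lower in depolarised Rem2 KO neurons by camera with the preset correlation (median -0.10, 10 of 39 members above 0, adjusted p = 1.71e-06). So were GABAergic (-0.08, 4 of 20 above 0, 0.000167), synaptogenic (-0.04, 0.000844), glutamate receptor (-0.10, 0.00232) and presynaptic (-0.03, 0.0336) lists by adjusted p. Lower too were the sodium and potassium channel (-0.06, 0.0136), calcium channel (-0.08, 0.0336), excitatory marker (-0.12, 0.0135) and microglia (-0.23, 0 of 13 above 0, 0.0279) lists. Under quantile normalization the calcium channel and excitatory marker lists did not pass camera (adjusted p = 0.068 and 0.0784). The p53 (0.20, 0.00342), proliferation (0.17, 0.0336) and oligodendrocyte (0.17, 0.0336) lists were higher. None held with an estimated correlation, where the smallest adjusted p was 0.252, and the 1 member that passed adjusted over its list alone was Grm2. With the block the endothelial list passed as well (adjusted p = 0.000323, and 0.360 with an estimated correlation), and the calcium channel and oligodendrocyte lists did not (adjusted p = 0.0581 and 0.0557).

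Averaged over both KCl states, 1 gene passed without the block, Igfbp7 (adjusted p = 0.00309), and 56 passed with it (10 higher and 46 lower in Rem2 KO). The unadjusted counts by limma were 328 and 1475 genes. Of the 56, 46 were detected in every library, 7 higher by 0.40 to 0.93 and 39 lower by log2 fold changes of -1.09 to -0.33 (median -0.54). Each of the 46 had the same direction in all 4 pairs of same-numbered libraries. The blocked fit that chose them favours such agreement, so it is no separate support. Within set 1 alone 2 genes passed and within set 2 alone 3, each with 1 residual degree of freedom (720 and 2018 at an unadjusted p under 0.05 by limma). With the block few of the 56 passed again when a library was left out: 22 without Rem2 KO replicate 1 (42 calls in all), 5 without its replicate 2 (9 calls), and 4 and 4 without Control replicates 1 and 2 (10 and 9 calls). Without replicates 1 and 2 of Control with KCl it was 9 and 10 (14 and 17 calls), and without those of Rem2 KO with KCl 5 and 4 (12 and 6 calls). All 56 genes stayed on their side of 0 in these fits, which reuse the libraries that chose the genes. Genes named from the blocked fit were chosen after their values were seen. Among genes detected in every library the largest fall was in Gpc5, a glypican proteoglycan (chromosome 14, 115092201 to 116525192), from 6.70 ± 2.00 to 2.41 ± 0.964 FPKM without KCl and from 6.48 ± 1.87 to 2.75 ± 0.961 FPKM with it (SD, n = 2; limma adjusted p = 0.00390 with the block and 0.983 without). Secreted or matrix genes Dcn (-0.96) and Rspo2 (-0.68), the melanocortin receptor gene Mc4r (-0.76), Ccdc85a (-0.75), the cell adhesion genes Pcdh7 (-0.63) and Lingo2 (-0.50), Slf1 (-0.65), Nwd2 (-0.59) and Plcxd2 (-0.57) also fell with the block. So did genes of transcription factors of cortical neurons, Zbtb18 (204 to 159 FPKM without and 180.1 to 106 with KCl, -0.56), Satb1 (28.6 to 20.6 and 31.3 to 21.4 FPKM, -0.49) and Foxp1 (16.4 to 11.8 and 14.6 to 11.0 FPKM, -0.41). The guanylate cyclase subunit gene Gucy1b1 was lower at 46.1 against 61.1 FPKM without and 46.9 against 67.3 FPKM with KCl (-0.46, adjusted p = 0.0167 with the block and 0.229 without). Rasl12 (0.93), Slc26a7 (1.25 to 3.32 and 1.33 to 2.78 FPKM, 0.82), Gpr153 (0.72), Lynx1 (0.71) and Mfap2 (0.40) rose with the block.

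Genotype effects without and with KCl correlated across the 12678 genes detected in every library at 0.424 (0.0831 over all 13089), and no gene passed in both states without the block. With the block Gpc5 passed in both. At an unadjusted p under 0.01 with the block and among genes detected in every library, 14 were higher and 58 lower in both states, against 0.524 and 2.02 for independent lists. Both lists come from 1 fit and share each gene's variance estimate, so these numbers are a reference and no test. Across the 12678 genes the averaged genotype effects of set 1 and set 2 correlated at 0.403, those without KCl at 0.142 and those with KCl at 0.347. Over all 13089 genes these were 0.170, 0.118 and 0.128. The share of all genes with the same sign in both sets was 53.3%, 47.2% and 58.3% in turn. The KCl effects of the 2 sets correlated across the 12678 genes at 0.903 in Control and 0.854 in Rem2 KO (0.695 and 0.614 over all 13089). On simulated data with 200 changed genes of 13089, the averaged contrast without the block recovered 55.4% of log2 changes of 1 and 5.60% of log2 changes of 0.5, and with the block 98.8% and 89.8%.

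**Figure D4:**
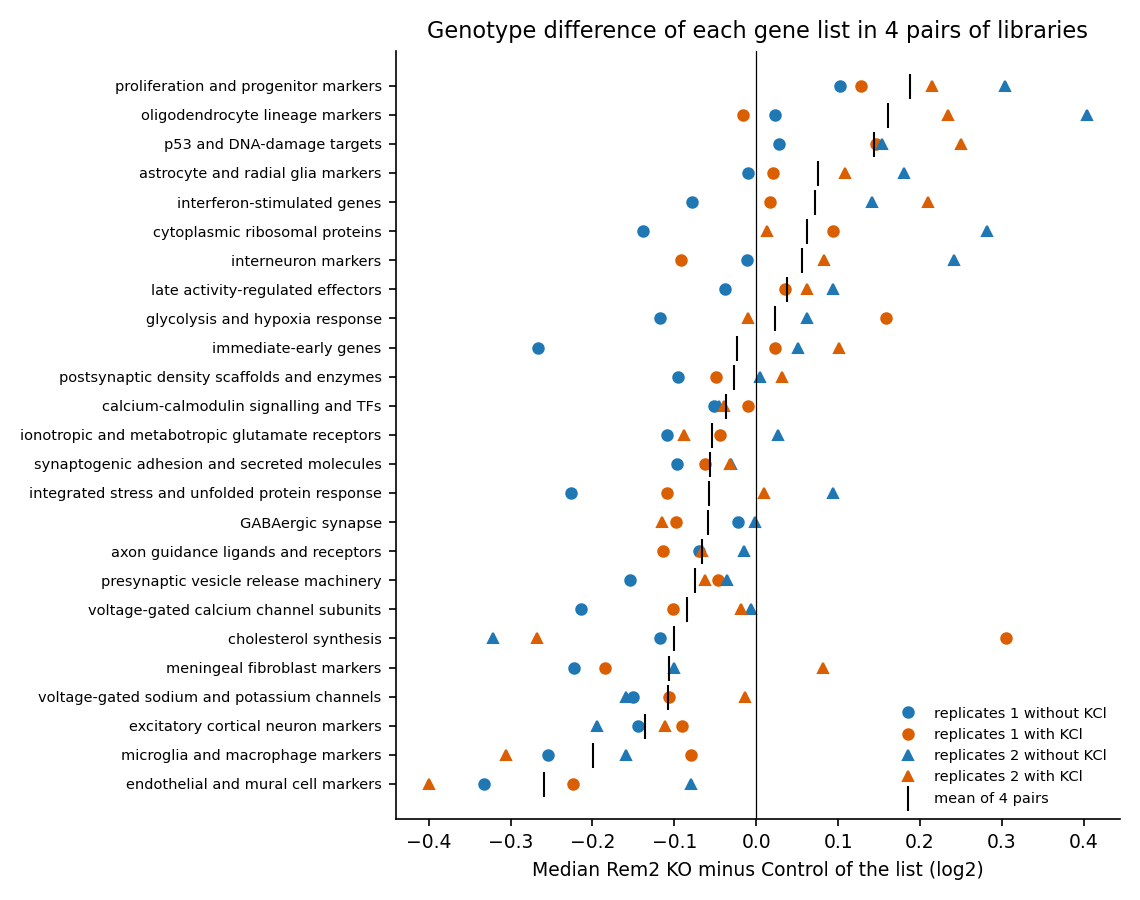
Median log2 difference between Rem2 KO and Control over the members of each gene list (horizontal), for the 4 pairs of same-numbered libraries, with bars for the mean of the 4 pairs. Microglia, endothelial, sodium and potassium channel and synaptogenic lists lie below 0 in every pair, and proliferation and p53 lists above 0 in every pair. The median of all genes tested was -0.07 and -0.004 in set 1 (without and with KCl) and 0.04 and 0.04 in set 2.

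By camera with the preset correlation, the averaged genotype effect was downward for 10 lists, 8 of them neuronal, and upward for 5. No list passed with an estimated correlation. The median of all genes tested was -0.07 and -0.004 in the pairs of set 1 without and with KCl. In set 2 it was 0.04 and 0.04. Sodium and potassium channels had a median of -0.10 (-0.15 and -0.11 in the pairs of set 1 without and with KCl, -0.16 and -0.01 in set 2; adjusted p = 2.65e-05, and 0.116 with an estimated correlation). Calcium channel subunits had a median of -0.08, with 3 of 15 above 0 (camera adjusted p = 0.000723, and 0.176 with an estimated correlation). Their pair medians were -0.21 and -0.10 in set 1 and -0.01 and -0.02 in set 2, below that of all genes in each pair. Among the members, Cacnb4 was at -0.32 and Cacna2d1 at -0.36. Axon guidance genes had a median of -0.06 (adjusted p = 0.000723, and 0.325 with an estimated correlation), and their members Sema7a (-0.41) and Robo2 (-0.37), a Slit receptor, fell with the block. The synaptogenic list had a median of -0.05 (27 of 76 above 0; adjusted p = 0.00177, and 0.381 with an estimated correlation), with Lrfn5 at -0.33 and Lrrtm3 at -0.40. Excitatory markers (-0.18, Foxp1 included; adjusted p = 0.00313), GABAergic (-0.06; 0.0068), presynaptic (-0.07; 0.0134, with Syt1 lower by the block at -0.33) and glutamate receptor genes (-0.09; 0.0194, with Cnih3 lower by the block at -0.43) were lower too, with adjusted p of 0.325, 0.325, 0.342 and 0.353 with an estimated correlation. Cholesterol synthesis genes had a median of -0.11 (0 of 20 above 0; adjusted p = 0.0134, and 0.594 with an estimated correlation), but the pair of set 1 with KCl went the other way (0.30, against -0.12, -0.32 and -0.27).

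Markers of other cell types differed by genotype in both directions. Some of these differences were larger in set 2. The median of all genes was also higher there (0.04 and 0.04 in its pairs, against -0.07 and -0.004 in set 1). All 18 proliferation and progenitor markers were above 0 (median 0.19; adjusted p = 0.00248, and 0.541 with an estimated correlation). So were all 17 markers of astrocytes and radial glia (0.09; 0.00177, and 0.381 with an estimated correlation) and 9 of 10 of the oligodendrocyte lineage (0.20; 0.00102, and 0.325 with an estimated correlation). In set 1 the pair medians were -0.01 and 0.02 for astrocytes and 0.02 and -0.02 for the oligodendrocyte lineage, against 0.18 and 0.11, and 0.40 and 0.23, in set 2. The p53 list (median 0.12, adjusted p = 0.00296, and 0.541 with an estimated correlation) was higher as well. Interneuron markers (0.06, adjusted p = 0.0452, and 0.410 with an estimated correlation) passed camera without the block, but not with it (0.171) or under quantile normalization (0.091). Their pair medians were -0.01 and -0.09 in set 1 and 0.24 and 0.08 in set 2. All 13 microglia markers (-0.19; 0.0426, and 0.681 with an estimated correlation) and all 9 endothelial and mural markers (-0.28; 0.0597, and 0.000599 with the block, 0.329 with that and an estimated correlation) were below 0. The immediate-early (adjusted p = 0.894), late effector (0.454), RGK (0.362), postsynaptic density (0.362, with Cnksr2 lower by the block at -0.37), calcium-calmodulin (0.143), interferon (0.368), integrated stress response (0.109), glycolysis and hypoxia (0.454), fibroblast (0.362) and ribosomal (0.214) lists did not pass. No list member passed over all genes without the block, and 4 passed adjusted over the list alone, Rem2 among RGK genes, Sema7a among axon guidance genes, Foxp1 among excitatory markers and Dcn among fibroblast markers. With the block adjusted over the list alone gave 1 higher and 17 lower synaptogenic genes, 2 and 8 presynaptic, 1 and 8 axon guidance, 1 and 6 glutamate receptor, 0 and 3 GABAergic, 1 and 4 calcium channel, 0 and 4 sodium and potassium channel and 1 and 5 excitatory marker genes. It gave 4 and 0 proliferation, 5 and 0 p53, 0 and 4 microglia and 0 and 2 endothelial genes, 2 and 2 in each of the postsynaptic density and calcium-calmodulin lists, and 0 and 1 in each of the RGK, late effector and fibroblast lists.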

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

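The tests of zeros, of Igfbp7, of endothelial markers and of the estimated correlation and block on these results were weighed here after the results were seen, although the interaction test, the block and the estimated correlation were themselves planned. The KCl effect of 1 gene and 6 gene lists differed between genotypes by the interaction test. Igfbp7 had a fitted interaction of 4.21 on the log2 scale, a size that depends on the pseudocount because the gene was listed at 0 in both Rem2 KO libraries. The lists, by camera with the preset correlation, were axon guidance (adjusted p = 0.000997), GABAergic synapse (0.00899), glutamate receptors (0.0229) and interneuron markers (0.0274) with a more negative KCl effect in Rem2 KO by that test, and cholesterol synthesis (0.000419) and immediate-early genes (0.0109) with a more positive one. With the block these were 0.01004 (axon guidance), 0.01004, 0.0963, 0.0111, 0.0111 and 0.0282, and with an estimated correlation 0.535 for each list but cholesterol synthesis (0.705), so no list difference held by that test. No biological explanation of the list differences was tested.

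Genotype calls made without the block within a KCl state were all genes listed at 0 in both libraries of a group, as Igfbp7, Dnlz and Surf1 were. Loss of Igfbp7 in Rem2 KO neurons in both KCl states is argued against by its log2 fold change of -0.16 (SE 0.12) with KCl, and loss of the non-neuronal cells that express it by endothelial and mural markers, whose lowest change without KCl was -0.48 (median -0.22). Failed estimates that hit whole groups irrespective of genotype remain a candidate explanation. Among 10662 genes reaching 5 FPKM, zeros set 1 group apart in 11, a Rem2 KO group in 4 and a Control group in 7 (exact binomial p = 0.549). Zeros followed the KCl state in 9 genes and the genotype in 0. The 11 genes are few and mixed, so the test cannot show an equal share. Mir1898, Mir218-1, Mir674, Mir7063 and Mir93 were above 0 in Control with KCl alone, and Dnlz in Rem2 KO alone. Of protein-coding genes, Dnlz, Igfbp7 and Surf1 set a Rem2 KO group apart and Agbl5 a Control group. A change of Igfbp7 by the knockout in silenced neurons alone stays open.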

How the results depend on the processing

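Tests restricted to genes above 0 in all libraries, the block combined with another choice, transcripts and the block without a library were chosen after the results were seen. Depth was known only roughly and the planned tests on counts were not run, so the precision that counts would give is unknown. A library left alone in its group was assumed to vary like the other groups. For the KCl effect, first in Control (2278 genes) and then in Rem2 KO (2099), the counts were 6367 and 6216 with the replicate block, 6703 and 6604 with the block and genes above 0, 6059 and 6031 with the block and quantile normalization, 6343 and 6184 with the block and pseudocount 0.1, 723 and 45 with only the 4 libraries compared, 1409 and 1379 for transcripts, and 126 to 1902 and 200 to 1412 in leave-one-out fits. For the genotype effect without KCl (3), with KCl (6), averaged (1) and the interaction (1), genes above 0 gave 0, 0, 0 and 0 by limma. The block gave 4, 10, 56 and 9, the block with genes above 0 11, 32, 110 and 0, with quantile normalization 5, 8, 43 and 9, with pseudocount 0.1 6, 10, 50 and 9, and transcripts 18, 0, 3 and 2. Leave-one-out fits gave 1 to 5, 0 to 4, 1 to 4 and 0 to 5, the first being 1 without Rem2 KO replicate 2 and 5 without Rem2 KO replicate 1. Only the 4 libraries compared gave 1 without and 0 with KCl. The effect with KCl was 2 with pseudocount 0.1, 0 with no filter, 0 with a minimum of 5 FPKM, 2 with upper quartile and 0 with TMM-type scaling. The averaged effect and the interaction were 4 and 4 with pseudocount 0.1, 2 and 2 with no filter and 2 and 2 with no variance trend, and the interaction was 2 with pseudocount 0.5. Lists passing for KCl in Control (12), KCl in Rem2 KO (10), averaged genotype (15) and interaction (6) numbered 1, 1, 0 and 0 with an estimated correlation and 0, 0, 0 and 0 with that and the block. Quantile normalization gave 7 and 6 for KCl (6 in Control with the block), and fry 1 and 0 for genotype and interaction (0 and 0 with the block). With the preset correlation the block changed no list call other than those given in the report. The slope of the KCl responses (1.00) was 0.953 over genes called in Control, 1.05 over those called in Rem2 KO, 0.993 with pseudocount 0.1 and 1.003 over genes above 0. Genes with a genotype effect in both KCl states (0 by limma) numbered 9 at an unadjusted p under 0.01, 1 with the block, 0 to 1 in leave-one-out fits and 72 with the block at that p over genes above 0. The Rem2 interaction (-0.015) reversed to 0.17 with pseudocount 0.1 (0.17 with the block too), 0.072 with pseudocount 0.5, and 0.017 to 0.51 (lowest -0.54, without Control replicate 1) without Control replicate 2, Control with KCl replicate 1, Rem2 KO replicate 1 (0.090) or Rem2 KO with KCl replicate 1 (0.024), and the averaged genotype effect of Vtn to 0.0098 without Rem2 KO replicate 1 (-0.60 without Rem2 KO replicate 2). Fits that leave some libraries out have fewer libraries, and leaving out 1 library also leaves its group with a library of 1 set alone. Why their counts were lower was not tested. The blocked counts of every contrast also moved when a library was left out. Of 72 and 73 named genes called for KCl in Control and Rem2 KO, 51 and 57 passed in every planned setting counted. That count did not cover the leave-one-out fits, the fit of only the 4 libraries compared or the fold of at least 1.5. No called gene reversed.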

Other observations

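The tests of cell-type markers and other splits were chosen after the results were seen, while those of gene length and of transcripts and copies were set before. Sets 1 and 2 differed in 6748 genes with the groups fitted (5276 higher and 1472 lower in set 2, median of all genes 0.14). Higher in set 2 were the proliferation genes Mki67 (6.34 to 22.3 FPKM) and Top2a (16.3 to 42.5 FPKM), Vim (234 to 694 FPKM), the microglial gene C1qa (3.19 to 10.1 FPKM), the interferon-stimulated genes Cxcl10 (1.54 to 13.5 FPKM) and Bst2 (1.75 on the log2 scale), Lcn2 (0.36 to 33.1 FPKM), and the smooth muscle gene Acta2 (5.33 to 66.1 FPKM), with Tagln listed at 0 in set 1. Ubb, Myl6 and Thra were listed at 0 in set 2. Ribosomal protein genes were lower in set 2 (median -0.84, 22 of 26 past the threshold, camera adjusted p = 1.91e-17), as were endothelial (-0.65, 0.00487), excitatory neuron (-0.17, 0.0023) and integrated stress response lists (-0.19, 0.0011), and interferon genes were higher (0.68, 0.00478), each with adjusted p = 0.576 with an estimated correlation.

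Reads assigned differently between copies or transcripts as the whole cause of the set difference are argued against, because 52.7% of protein-coding genes with a single transcript differed against 49.5% (49.45) of the others. More progenitors and microglia in the cultures of set 2 is a candidate explanation for part of it. All 13 microglia markers passed as higher (median 0.73, camera adjusted p = 0.00189). Of 18 proliferation markers 14 passed as higher and 1, Pax6 (-0.19), as lower (median 1.00, camera adjusted p = 0.0011). With an estimated correlation the adjusted p was 0.576 for each list. The labels name no difference between the sets, and a different library batch or depth stays open.

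The averaged genotype effect with the block passed in 55 genes in an additive fit, and 1 of the 33 splits of the libraries that could be fitted, the real one, gave as many (highest other 35; over genes above 0 in all libraries 128, highest other 4, and 0 among splits parting all pairs). Replicate numbers pair the libraries, and of the splits that part all 4 pairs there are 8 (highest other 2), too few for a share under 0.05, while the others break pairs. Without the block the real split gave 0 genes in the additive limma fit (the fit of 4 groups gave 1, and 328 at an unadjusted p under 0.05), which any of the 34 splits equals or exceeds, so that count says nothing about chance, and the highest, 6752, followed the sets, a structure of the libraries. The median change of proliferation markers exceeded that of microglia markers by 0.39 (SD 0.14, with 0.36, 0.21, 0.46 and 0.52 in the pairs). This argues against a lower share of neurons with every other cell type raised alike in the Rem2 KO cultures. It cannot decide on a lower share of neurons through more progenitors, which would leave such a gap too. A trend with gene length as the whole cause is argued against as well: after its removal 35 of the 56 genes passed, and the 21 others went from a median log2 size of 0.50 (SE 0.0638) to 0.46 (SE 0.0645) and a median adjusted p of 0.0497 to 0.0678. An effect of the knockout on these genes, more progenitors (with them a lower share of neurons) or fewer microglia in the Rem2 KO cultures, and a difference between the animals behind the genotypes stay open, the last untested.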
